A study of Homo sapiens with 6 samples.

How the data were processed

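The samples were 6 RNA preparations from MNNG-HOS, an established human osteosarcoma cell line. Per the labels, 3 came from cells that stably overexpressed SPARCL1, a secreted matricellular glycoprotein related to SPARC, and 3 from cells with an empty vector. Per the labels' protocols, total RNA was isolated with TRIZOL, checked for integrity on a Bioanalyzer, cleaned on RNeasy columns with DNase treatment, and labelled with the Low Input Quick Amp kit for one-colour arrays. The labels do not say whether the replicates of a group were separate cultures. Every p-value therefore measures only the spread between these samples, which is possibly technical.

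Each sample was hybridized to 1 Agilent array of design 72363 with 62976 spots, of which 60901 were not controls, and probes of 60 bases. Per the file headers, the spots were read with Agilent Feature Extraction 10.7.1.1, and the deposited processed intensity of each spot was background-subtracted and detrended within its array, with dim spots given a surrogate value and no scaling between arrays. Per the submitters' processing notes, Agilent Feature Extraction 10.7 and limma were used, and limma's role is not given. The authors also deposited a value table whose values lay on a log2 scale. The method behind it is not stated. Its array medians lay between 4.17 and 4.175, and its values correlated with log2 processed signal on the same array at r = 0.99777 to 0.99996 across probes, which are not independent replicates. The spot flags for outliers, saturation and signal well above background came from the deposited scanner files and are 0 or 1.

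The processed intensity was taken to log2, and the 75th percentile over the non-control spots of each array was subtracted, so that a normalized level of 0 is that percentile. Spots called outliers by the scanner software were left out, which removed 11 probes, and the 300 probes with 10 spots each were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which kept 29070 of 58201 probes. Gene names came from a reference table of RefSeq genes on the assembly GRCh38.p14, used for names only. With it, 31104 probes were named by transcript accession, 3862 by symbol, while 23235 had no match and were kept as unnamed features. The probe with the highest mean level stood for its gene. This gave 16169 genes and 6789 unnamed features. Probe positions are those of the array files, on hg19 (GRCh37).

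The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend), with jsonlite 2.0.0 and the R package data.table (version 1.17.8) for reading files. All tests were two-sided. P-values were adjusted by Benjamini and Hochberg over all 22958 features, and a gene counted as changed at an adjusted p under 0.05. Fold changes are SPARCL1 against vector. Where none of the arrays of the dimmer group was well above background, the fold is a bound. An adjusted p printed beside a bound belongs to the fitted difference. Counts of changes of at least 2-fold use fitted values for all genes. The mean of the brighter group was set against a mean over the arrays of the dimmer group. Each of these arrays entered with the higher of 2 levels: the gene's own, and the lowest of any probe called well above background on that array. These lowest levels ran from -4.54 to -4.17 on the SPARCL1 arrays and from -4.88 to -4.63 on the vector arrays. Dimmer genes could therefore pass the filter through the vector group. Array signal over background and the number of arrays limit the precision. The prior degrees of freedom were 2.155 beside 4 residual ones.

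Before the data were examined, the tests, the filter, 42 gene lists, a list of genes tied to the question, and the rule for naming genes were fixed. The rule took the fixed genes, the 12 largest rises and 12 largest falls with no overlap between the groups' values and a symbol that is not systematic, up to 4 members of each list with the smallest adjusted p, and up to 6 members of lists that passed their test. Genes outside the rule are said to be chosen later where they are named. Not all genes that the rule took are reported here. Lists were tested with camera at its preset correlation of 0.01 and adjusted over the 42 lists. Camera with an estimated correlation and fry were alternatives. The p-value of fry tests whether the genes of a list moved on balance one way and does not compare the list with other genes.

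The file headers place the arrays on 2 slides. SPARCL1 replicates 1 and 2 were on slide 1, and SPARCL1 replicate 3 and the 3 vector arrays were on slide 2. Slide 1 held samples of 1 group only, so the only comparison within a slide is that of SPARCL1 replicate 3 with the vector arrays. The fit with slide as a block takes its difference between groups from slide 2 alone, and its residual spread from both slides. Within slide 2 the spread comes from the 3 vector arrays alone, and the lone SPARCL1 array is assumed to vary like them, although the SPARCL1 arrays varied more (median SD over genes 0.107 against 0.0818). Both fits are given beside the results. Without SPARCL1 replicate 3, slide and group cannot be told apart.

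The alternatives were normexp background correction with an offset of 50, quantile normalization, array median scaling, the authors' value table, no filter, a filter on all 6 arrays, the mean over a gene's probes, an intensity trend, robust variance, array weights, the replicate number as a block, slide as a block, leaving out each array in turn, and unadjusted p-values. Scaling by the percentile over detected probes and the fit within slide 2 were added after the files had been read. The fit was tested on simulated data built on the 22958 features of SPARCL1 against vector: it recovered 43.3% of 67 genes changed 1.5-fold, 70.2% of 67 changed 2-fold and 90.9% of 66 changed 4-fold, and 6 of 142 calls were false. The simulated noise was independent between genes and held no slide difference, and far fewer genes changed than were called in the data. These shares therefore may not hold for the real comparison.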

Results

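Gene expression was measured in the osteosarcoma line MNNG-HOS on one-colour arrays, with 3 SPARCL1-overexpressing and 3 vector samples. The question, from the series' title, was how SPARCL1 overexpression affects these cells; SPARCL1 in osteosarcoma has been studied with a view to WNT/β-catenin signalling and macrophage recruitment through CCL5. Spots well above background made up 49.7%, 48.9% and 53.6% of all spots on SPARCL1 arrays 1 to 3, and 56.6%, 53.8% and 54.0% on vector arrays 1 to 3. No spot was saturated. The 75th percentile of the processed signal ran from 285 to 371.7 intensity units.

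The arrays held 1 probe for SPARCL1 itself, at chromosome 4, 88394538 to 88394597 (hg19, minus strand), starting at base 2794 of its transcript NM_004684. It was not well above background on any of the 6 arrays. Its normalized log2 level was -6.33 ± 0.21 (SD, n = 3) in the SPARCL1 arrays and -6.74 ± 0.15 (SD, n = 3) in the vector arrays, both at the floor of detection, so no fold is given. Whether the expressed construct holds the stretch that the probe reads is not stated. The probe therefore checks nothing about the labels.

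The metallothionein genes, which code for small metal-binding proteins, gave the largest rises, and ANGPT2, IL24 and the noncoding RNA UCA1 were among the largest falls. MT1G, at chromosome 16, 56700694 to 56700752 (minus strand), rose 13.8-fold (log2 fold change 3.79 ± 0.09 SE, adjusted p = 6.45e-05, limma), from a level of 0.89 ± 0.12 to 4.68 ± 0.09 (SD, n = 3 each). ANGPT2, a ligand of the TIE2 receptor that acts on blood vessels, at chromosome 8, 6360290 to 6360349 (minus strand), fell 16.4-fold (log2 fold change -4.03 ± 0.09 SE, adjusted p = 6.45e-05), from 1.87 ± 0.04 to -2.16 ± 0.16. Of 23 genes of cholesterol synthesis and uptake 19 rose and none fell, and of 23 genes of the ATF4 amino acid stress response 10 fell and 3 rose. Both lists passed camera at its preset correlation and neither with an estimated one (adjusted p = 0.717 with an estimated correlation for each).

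In total 3756 of 16169 genes (23.2%) changed, 1927 up and 1829 down. Of them 384 had a fitted change of at least 2-fold, 97 up and 287 down. These 2-fold counts include genes at background in 1 group whose bound is smaller, such as AKR1C4 (at least 1.96-fold). At an unadjusted p under 0.05 there were 6400 genes. The values of the groups did not overlap in 7648 genes (47.3%), where chance gives 10%. The split of directions moved with the scaling: array median scaling shifted the median log2 fold change of all genes to 0.12, against 0.01 with the percentile, and gave 1656 rises and 892 falls. The percentile over detected probes gave 1445 rises and 2590 falls. Falls made up 74.7% of the 2-fold changes, 81.8% with the percentile over detected probes, 68.8% under quantile normalization, 69.5% in the authors' table, 61.8% under median scaling and 57.6% under normexp (92 genes). Among genes well above background on all 6 arrays, a filter that leaves out genes that fell to background or rose from it, 158 of 241 such changes were falls (65.6%). The share differed with level: 260 of 330 were falls among genes with a mean level below the median of all tested genes, and 27 of 54 among those above it.

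With slide as a block 1698 genes passed, 710 up and 988 down, and 1474 of them were among the 3756. Within slide 2 alone, where SPARCL1 replicate 3 faced the 3 vector arrays, 1656 passed, 661 up and 995 down, and 1398 of them were shared. At least 2-fold changes numbered 395 with the block and 420 within slide 2. Both fits take their difference from the lone SPARCL1 array of slide 2, which is also part of the fit over all arrays, so shared calls and directions are not independent evidence. Within slide 2 the spread comes from the vector arrays alone, and the lone array is assumed to vary like them. The SPARCL1 arrays varied more, with a median SD over genes of 0.107 against 0.0818, so the p-values within slide 2 are too small to the extent that the lone array shares this spread. The count of changed genes was 2372 without SPARCL1 replicate 1 and 2813 without SPARCL1 replicate 2. It was 1903 without vector replicate 1, 1844 without vector replicate 2 and 2039 without vector replicate 3. Without SPARCL1 replicate 3 it rose to 3902, against 3756 over all arrays, although an array was lost. Slide and group coincide in that fit, so a share of slide in its calls cannot be told apart. SPARCL1 replicate 3 also had the lowest array weight (0.452, against 0.77 to 1.94 on the other arrays). Loss of a more variable array may therefore also bear on the count, which was not tested. The first principal component carried 61.2% of the variance and parted the groups, with scores of -28.5, -28.6 and -19.8 for the SPARCL1 arrays and 24.3 to 27.0 for the vector arrays. Arrays of the vector group correlated at 0.997 to 0.998 across genes, those of the SPARCL1 group at 0.993 to 0.995, and pairs between groups at 0.988 to 0.98981.

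**Figure D1:**
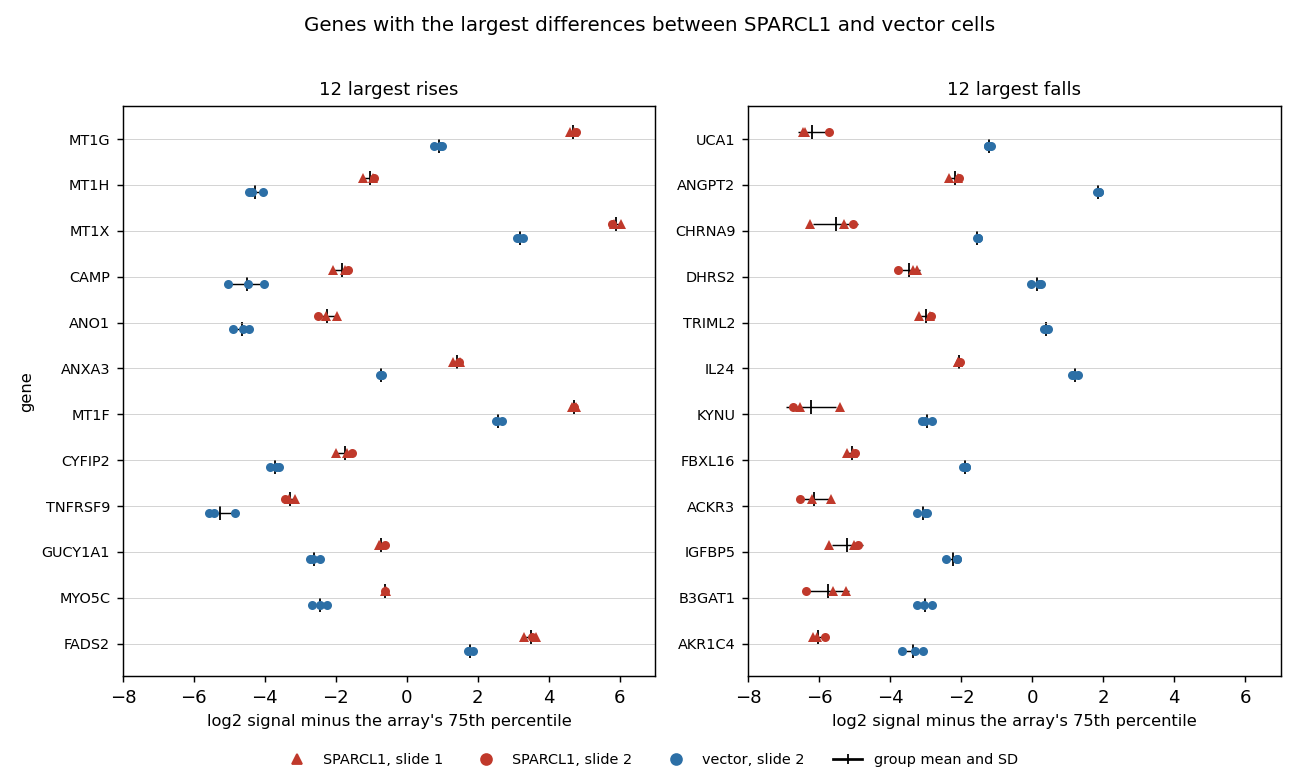
Normalized log2 level (x axis: log2 signal minus the 75th percentile of the array) of the 12 genes with the largest rises and the 12 with the largest falls, with 1 symbol per array (SPARCL1 in red, vector in blue, n = 3 each; triangles for slide 1, circles for slide 2) and group means with SD. MT1G lies near 4.68 in the SPARCL1 arrays and near 0.89 in the vector arrays, and UCA1 lies below the floor of detection in the SPARCL1 arrays.

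Among the 12 largest rises, 4 were metallothioneins: beside MT1G, MT1X rose 6.48-fold, MT1F 4.40-fold and MT1H 9.48-fold, the last with 2 of 3 vector arrays above background. CAMP, the gene of the antimicrobial peptide cathelicidin, rose 6.42-fold (log2 fold change 2.68 ± 0.27 SE, adjusted p = 0.00241) with 1 of 3 vector arrays above background. ANO1, a calcium-activated chloride channel, was at least 4.97-fold higher, and TNFRSF9, a costimulatory receptor, at least 2.64-fold higher. ANXA3 rose 4.40-fold, CYFIP2 3.93-fold, the guanylate cyclase subunit gene GUCY1A1 3.71-fold, the myosin gene MYO5C 3.58-fold and the fatty acid desaturase gene FADS2 3.25-fold.

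Among the 12 largest falls, UCA1, at chromosome 19, 15946035 to 15946092 (plus strand), was at least 8.61-fold lower (adjusted p = 0.000298 for the fitted difference, limma). CHRNA9, a nicotinic acetylcholine receptor subunit gene, was at least 6.83-fold lower and FBXL16 at least 5.37-fold lower. DHRS2 fell 12.1-fold, TRIML2 10.4-fold and the cytokine gene IL24 9.65-fold. The growth factor-binding protein gene IGFBP5 was at least 4.27-fold lower, the kynureninase gene KYNU at least 2.54-fold, B3GAT1 at least 2.44-fold, the CXCL12 scavenger receptor gene ACKR3 at least 2.36-fold and AKR1C4 at least 1.96-fold. The order follows fitted values, which are no bound for genes at background in 1 group, and falls measured on all arrays, such as COL4A6 (5.62-fold) and MMP1 (5.35-fold), exceeded several of these bounds. Within slide 2 ANGPT2 stood at -3.93 and MT1G at 3.86.

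**Figure D2:**
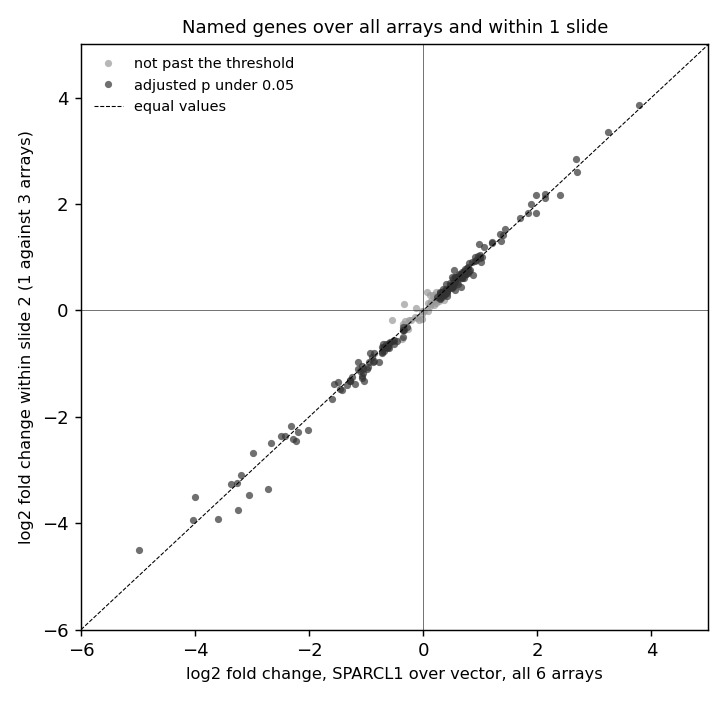
Log2 fold change of the named genes over all 6 arrays (x axis) and within slide 2 alone, SPARCL1 replicate 3 against the 3 vector arrays (y axis), with 1 point per gene, dark where the adjusted p over all arrays was under 0.05, and a dashed line at equal values. The axes share the arrays of slide 2, so the values are not independent. The highest point is MT1G (3.79 and 3.86), and the lowest is UCA1, whose fitted values are no bound since it lay below the floor in the SPARCL1 arrays.

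The fixed lists were compared with all other genes by camera, and 8 of 42 passed, 7 of them upwards. Among the 7 were histone genes, mitochondrial transcripts and ribosomal proteins, lists fixed as signs of RNA handling and scaling. None of the 8 passed with a correlation estimated from the data (camera), where the lowest adjusted p was 0.717. With fry, which does not compare a list with other genes, 25 passed. The median log2 fold change climbed with mean level, from -0.126 over the 4043 dimmest tested genes to 0.0725 over the 4042 brightest. Camera did not match the lists to other genes in level, so a share of this trend in the upward calls was not tested. The median of the G1/S and DNA replication genes (0.09) lay near that of the brightest genes. Each list below is given with its members that passed over all genes tested and with those adjusted over the list alone.

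Cholesterol synthesis and uptake was the list with the smallest p. Of its 23 members 10 rose and none fell with slide as a block. Over all arrays 19 rose and none fell, and 21 rose adjusted over the list alone (adjusted p = 3.05e-10, or 0.717 with an estimated correlation). Its median log2 fold change was 0.55, and 0.46 within slide 2, with adjusted p = 3.08e-08 with slide as a block and 7.83e-08 within slide 2. INSIG1, which retains the SREBP transcription factors in the endoplasmic reticulum when sterols are high, rose by 1.40, the squalene epoxidase gene SQLE by 0.92 and DHCR7 by 0.78 on the log2 scale.

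Of 12 metallothionein-list members 9 rose and 1 fell, the same numbers adjusted over the list alone (adjusted p = 5.38e-06, or 0.717 with an estimated correlation). The median was 0.78 over all arrays and within slide 2, with adjusted p = 1.73e-05 with slide as a block and 1.09e-05 within slide 2. Beside the largest rises, MT1M rose by 1.07. MT1E rose by 0.91, with another of its probes pointing the other way. MT2A (0.16) and MT3 (0.21) did not pass. The member that fell was SLC30A1, which codes for a zinc exporter of the cell membrane, by 1.13. MT2A and MT3 were chosen after their values were seen, and SLC30A1 had been named for a test before its value was seen.

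The lists of histone genes, whose transcripts mostly lack a poly(A) tail, of mitochondrial transcripts, of ribosomal proteins and of reference genes had been fixed as signs of RNA handling and scaling. All but the reference genes passed at the preset correlation. A difference in RNA handling or scaling between the groups therefore cannot be told apart from a change in the cells. Of 50 replication-dependent histone genes 8 rose and 1 fell with slide as a block. Over all arrays 28 rose and 2 fell, or 33 and 4 adjusted over the list alone (adjusted p = 1.66e-06, or 0.717 with an estimated correlation). The median was 0.51, and 0.46 within slide 2 (adjusted p = 2.22e-05 with slide as a block, 7.86e-06 within slide 2). H1-1 rose by 1.21, H2AC14 by 0.79 and H2AC20 by 0.77, and H2BC12 fell by 0.58. Whether histone probes read each other's transcripts was not tested, so the rises may not be separate. Of 11 mitochondrially encoded transcripts 3 rose and none fell with slide as a block. Over all arrays 7 rose and none fell, or 8 and 0 adjusted over the list alone (adjusted p = 0.000815, or 0.717 with an estimated correlation). Their median was 0.38, and 0.36 within slide 2 (adjusted p = 0.0102 with slide as a block, 0.0156 within slide 2), with ND5 up by 0.64 and ND2 by 0.49, both subunits of respiratory complex I.

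The cytosolic ribosomal protein list also passed (adjusted p = 8.17e-05, or 0.717 with an estimated correlation), with a median of 0.18, and 0.17 within slide 2 (adjusted p = 0.00267 with slide as a block, 0.00206 within slide 2). In it 4 of 51 members rose, RPL3 by 0.53, RPL34 by 0.35, RPS12 by 0.30 and RPS28 by 0.29, and none fell, while 0 passed adjusted over the list alone. The call was lost under quantile normalization (adjusted p = 0.866), and in the authors' value table the median was -0.00 (adjusted p = 0.996). The 4 rises did not pass with slide as a block or under quantile normalization. Of 37 G1/S and DNA replication genes 8 rose and 1 fell, or 10 and 2 adjusted over the list alone (adjusted p = 0.0315, or 0.74 with an estimated correlation). This call did not pass with slide as a block (adjusted p = 0.396) or within slide 2 (0.483), nor without SPARCL1 replicate 1 (0.0867), SPARCL1 replicate 2 (0.0993) or vector replicate 2 (0.108). It held in 7 of 19 settings, over which the adjusted p ran from 0.00893 to 0.483, and its median was 0.09, or 0.07 within slide 2. Of 36 G2/M genes 1 rose and 2 fell, the same numbers adjusted over the list alone (adjusted p = 0.52), and the proliferation marker MKI67 stood at 0.06 (0.35 within slide 2, and -0.01 with the percentile over detected probes) without passing.

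The list of ATF4 and amino acid stress genes moved down: 10 of 23 members fell and 3 rose, or 12 and 3 adjusted over the list alone (adjusted p = 0.00791, or 0.717 with an estimated correlation). Its median was -0.27, and -0.38 within slide 2 (adjusted p = 0.00214 with slide as a block, 0.00208 within slide 2). CTH, which makes cysteine from cystathionine, fell by 1.28, the transcription factor genes DDIT3 by 0.99, ATF3 by 0.86 and CEBPB by 0.65, the cystine transporter gene SLC7A11 by 0.94 and the amino acid transporter gene SLC7A5 by 0.60. Of 23 NRF2 target genes 8 fell and 2 rose, or 10 and 4 adjusted over the list alone (adjusted p = 0.178). AKR1C3 fell by 2.28 and the heme oxygenase gene HMOX1 by 1.07.

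Of 29 hypoxia and glycolysis genes 3 rose and 2 fell with slide as a block. Over all arrays 11 rose and 3 fell, or 15 and 3 adjusted over the list alone (adjusted p = 0.0177, or 0.717 with an estimated correlation). The median was 0.20, and 0.23 within slide 2. The call was lost with slide as a block (adjusted p = 0.0807), within slide 2 (0.107), under normexp (0.0762), under quantile normalization (0.0857) and in the authors' table (0.101), and over 19 settings the adjusted p ran from 0.00916 to 0.107. ENO2 rose by 0.71 and PDK1 by 0.51, while ANGPTL4 fell by 0.97 and LOX by 0.66.

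**Figure D3:**
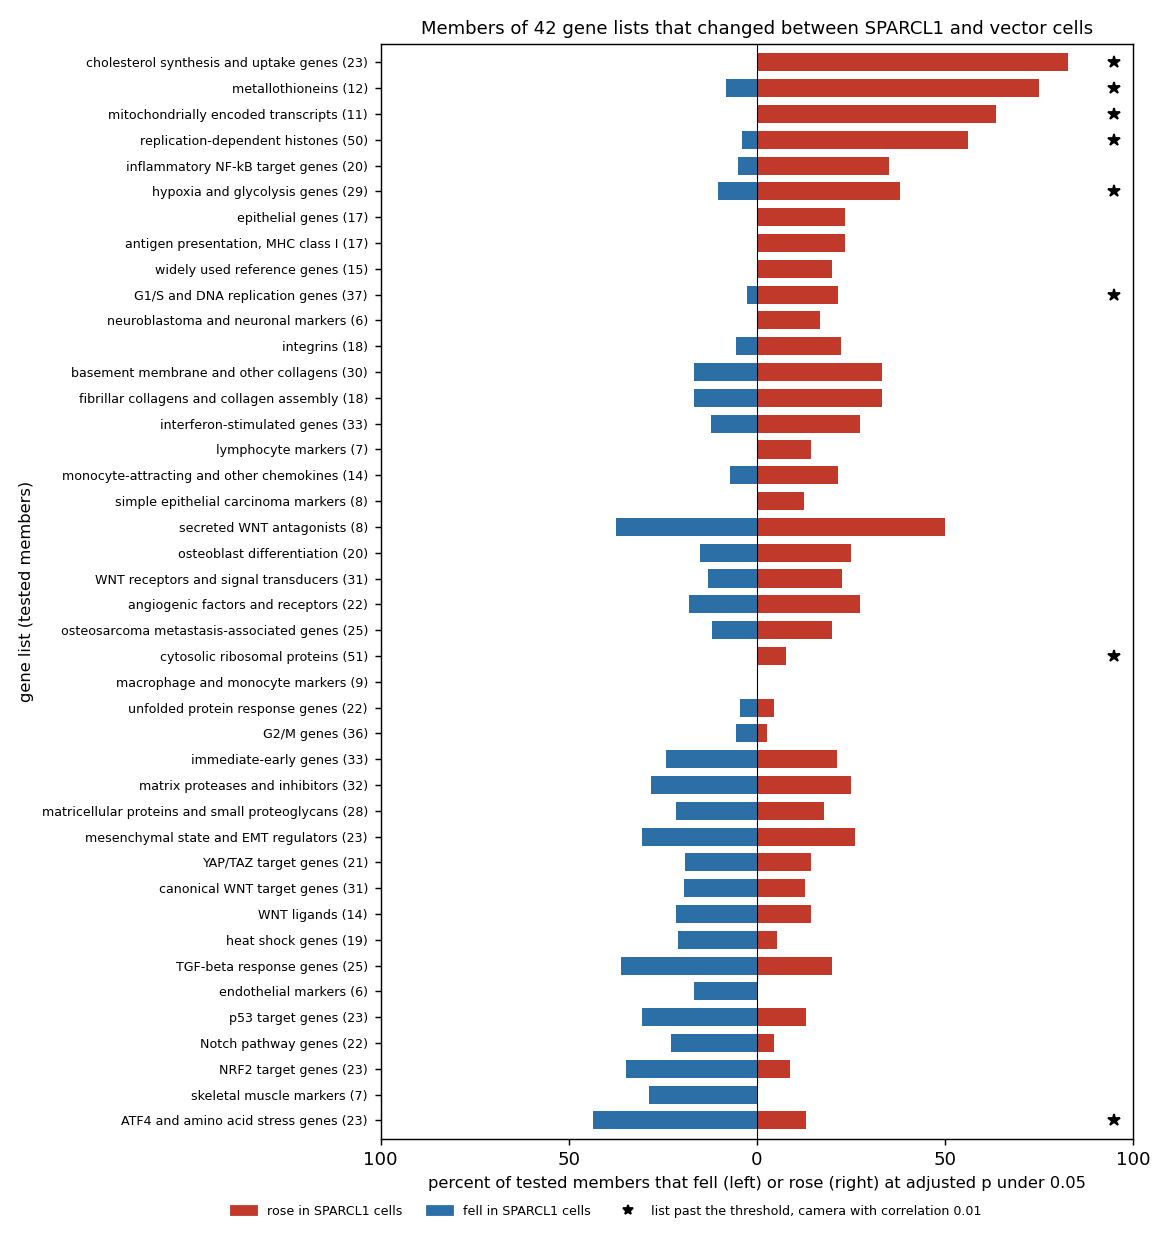
Percent of the tested members of each of the 42 fixed lists (x axis) that fell (blue, left) or rose (red, right) at an adjusted p under 0.05, with the number of tested members in brackets and a star where the list passed camera at a correlation of 0.01. Among cholesterol synthesis and uptake genes 19 of 23 rose, and among ATF4 and amino acid stress genes 10 of 23 fell.

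The WNT question was addressed with 4 lists, none of which passed. Of 31 canonical WNT target genes 4 rose and 6 fell, or 6 and 7 adjusted over the list alone (adjusted p = 0.913, median -0.02). AXIN2, a direct target of β-catenin and its negative regulator, rose by 0.55 (SE 0.08, adjusted p = 0.00636), and by 0.64 within slide 2 (adjusted p = 0.0254 with slide as a block), while PTGS2 fell by 0.73 and BAMBI by 0.63. LEF1 (-0.02), DKK1 (-0.02), MYC (-0.07), CCND1 (0.09), LRP6 (0.09) and RUNX2 (-0.03) did not pass, and under array median scaling LEF1, DKK1, MYC and RUNX2 had a value above 0 without passing. CTNNB1, the gene of β-catenin, rose by 0.30 (adjusted p = 0.036; 0.101 with slide as a block), a call lost in 12 of 20 alternatives with adjusted p from 0.00892 to 0.119, among them quantile normalization, the authors' table and the percentile over detected probes. FZD8 fell by 0.35 (adjusted p = 0.0179; 0.0793 with slide as a block), a call lost in 9 of 20 with adjusted p from 0.00501 to 0.19, among them array median scaling. NKD1 and RNF43 did not reach the level for testing.

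Among WNT ligands 2 of 14 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.972), with WNT5A up by 0.70, WNT7B up by 0.97, WNT6 down with a log2 fold change of -1.05 and RSPO4 with -0.63. Of 31 WNT receptors and signal transducers 7 rose and 4 fell, or 9 and 4 adjusted over the list alone (adjusted p = 0.178). LGR4, a receptor for R-spondins, rose by 0.74 and FZD7 by 0.52, while TCF7L1 fell by 0.88 and the WNT5A receptor gene ROR2 by 0.89. Of 8 secreted WNT antagonists 4 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.909). FRZB fell by 2.20 and KREMEN2, a cell-surface DKK receptor, by 1.28, while SFRP1 rose by 1.003 and SERPINF1 by 0.63 on the log2 scale. The median of this list was 0.24 and its mean -0.05.

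The macrophage question could be addressed only in part. CCL5 lay at -6.14 ± 0.85 in the SPARCL1 arrays and -6.11 ± 0.21 in the vector arrays (SD, n = 3 each), and neither it nor CCL2 was well above background on any array, so a difference was not detectable. CXCL8 was above background on 1 vector array. CSF1, the macrophage growth factor gene, stood at 0.12 without passing. Of 14 monocyte-attracting and other chemokines 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.406). CSF2 rose by 0.66, CXCL1 by 0.80 and VEGFA by 0.53, and CXCL12 fell by 0.45. With slide as a block the adjusted p was 0.116 for CXCL1 and 0.0908 for CXCL12, and CSF2 was at 0.0515 within slide 2. Of 20 alternatives, 17 lost the call of CXCL12 (adjusted p from 0.023 to 0.219; -0.14 under normexp), 9 that of VEGFA (0.00885 to 0.114), among them quantile normalization and the authors' table, 8 that of CXCL1 (0.00647 to 0.137) and 2 that of CSF2 (0.0041 to 0.0523).

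Of 20 inflammatory NF-kB target genes 7 rose and 1 fell, or 9 and 2 adjusted over the list alone (adjusted p = 0.178), with TNFAIP3, an inhibitor of NF-kB signalling, up by 0.61, IRAK2 by 0.56 and CD83 by 0.52. Of 33 interferon-stimulated genes 9 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.714). IFIT1 rose by 1.34, IFIT2 by 0.86 and OASL by 0.81, and IFI44L was at least 1.02-fold lower. Of 17 genes of MHC class I antigen presentation 4 rose and none fell, also adjusted over the list alone (adjusted p = 0.311), with the immunoproteasome gene PSMB8 and the peptidase gene ERAP1 each up by 0.55.

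Genes of the extracellular matrix moved both ways. Of 32 matrix proteases and inhibitors 8 rose and 9 fell, or 10 and 11 adjusted over the list alone (adjusted p = 0.611). MMP9, a gelatinase, rose 2.29-fold (log2 fold change 1.20 ± 0.08 SE, adjusted p = 0.000865; 1.26 within slide 2, and adjusted p = 0.00891 with slide as a block). The collagenase gene MMP1 fell by 2.42 and TIMP3, an inhibitor of such proteases, by 1.46, while ADAM8 rose by 1.35. MMP2 rose by 0.55 (adjusted p = 0.014), and by 0.38 within slide 2 without passing (adjusted p = 0.085 with slide as a block), a call lost in 6 of 20 alternatives (0.00443 to 0.085). Of 18 genes of fibrillar collagens and collagen assembly 6 rose and 3 fell, or 7 and 3 adjusted over the list alone (adjusted p = 0.611), with COL1A1 up by 0.91, COL5A1 by 0.68 and LOXL1 by 0.59. Of 30 basement membrane and other collagens 10 rose and 5 fell, or 12 and 5 adjusted over the list alone (adjusted p = 0.188). COL4A6 fell by 2.49 and COL4A5 by 1.07, and COL8A1 rose by 1.44. Of 28 matricellular proteins and small proteoglycans, the class of SPARCL1, 5 rose and 6 fell, or 7 and 7 adjusted over the list alone (adjusted p = 0.998). FBN1 rose by 0.96 and EFEMP1 by 0.64, SMOC1 fell by 0.86 and THBS1 by 0.71, and SPARC stood at 0.02 without passing and slightly below 0 under 3 of the other scalings. Of 18 integrins 4 rose and 1 fell, or 6 and 2 adjusted over the list alone (adjusted p = 0.723), with ITGB2 up by 0.87 and ITGB3 down with -0.69.

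Genes of cell state and spread were also mixed. Of 23 mesenchymal state and EMT regulators 6 rose and 7 fell, or 7 and 8 adjusted over the list alone (adjusted p = 0.723). The transcription factor gene SNAI2 fell by 1.28 and PRRX1 rose by 1.04. VIM (0.17) did not pass and lay at -0.01 under quantile normalization and -0.00 in the authors' table, and CDH2 rose by 0.39 (adjusted p = 0.0165; 0.107 with slide as a block), a call lost in 7 of 20 alternatives (0.0028 to 0.126). Of 17 epithelial genes 4 rose and none fell, also adjusted over the list alone (adjusted p = 0.462), with PKP3 up by 0.75. Of 20 osteoblast differentiation genes 5 rose and 3 fell, or 6 and 3 adjusted over the list alone (adjusted p = 0.611). The osteopontin gene SPP1 fell by 1.15, and ENPP1, which makes the mineralization inhibitor pyrophosphate, rose by 0.67, as did the osteoprotegerin gene TNFRSF11B by 0.65. Of 25 osteosarcoma metastasis-associated genes 5 rose and 3 fell, or 5 and 4 adjusted over the list alone (adjusted p = 0.746). IGF2 rose by 0.74, ACKR3 fell as above, and MET rose by 0.32 (adjusted p = 0.0293; 0.107 with slide as a block), a call lost in 13 of 20 alternatives (adjusted p from 0.00663 to 0.117), among them quantile normalization, the authors' table and the percentile over detected probes. Of 22 angiogenic factors and receptors 6 rose and 4 fell, or 7 and 4 adjusted over the list alone (adjusted p = 0.913), with PGF down with -1.05 beside ANGPT2.

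Lists of other cell types held few measured members and did not pass. None of 9 macrophage and monocyte markers changed, also adjusted over the list alone (adjusted p = 0.723 for the list). Of 7 lymphocyte markers 1 rose (CD4, by 0.47, lost in 8 of 20 alternatives, with slide as a block at 0.0854), also adjusted over the list alone (0.723), of 8 simple epithelial carcinoma markers 1 rose, also adjusted over the list alone (0.923), and of 6 neuroblastoma and neuronal markers 1 rose (0.843), or 1 rose and 1 fell adjusted over the list alone. Of 6 endothelial markers 1 fell, EGFL7 by 1.43, or 1 rose and 2 fell adjusted over the list alone (adjusted p = 0.462). Of 7 skeletal muscle markers 2 fell, among them the embryonic myosin gene MYH3 by 0.72, also adjusted over the list alone (adjusted p = 0.311). Of 15 widely used reference genes 3 rose and none fell, or 4 and 0 adjusted over the list alone (adjusted p = 0.271). They were GUSB (0.42), SDHA (0.33) and ACTB (0.25), and none of the 3 passed with slide as a block. The call of ACTB was lost in 16 of 20 alternatives (adjusted p from 0.0224 to 0.538), that of SDHA in 11 (0.00601 to 0.164) and that of GUSB in 4 (0.00116 to 0.085).

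The 34 lists that did not pass had medians between -0.22 and 0.24 over all arrays and between -0.24 and 0.37 within slide 2, and none passed with slide as a block (lowest adjusted p = 0.0865) or within slide 2 (0.107). The median, the mean and the direction of camera differed in sign in 8 of them: secreted WNT antagonists, matricellular proteins, metastasis-associated genes, YAP/TAZ targets, Notch genes, angiogenic factors, heat shock genes and lymphocyte markers. Of the named genes that had passed, 120 of 177 kept direction and call under every alternative that gave them a value, and 1 reversed.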

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

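The slide test of the metallothioneins and the level and scaling tests of the falls were chosen after the result was seen, and the limits of the level test were set again once its values were known. Features without a gene symbol entered the fit and the adjustment of p-values but none of the counts of the report, and also held signal: 838 of 6789 changed, 365 up and 473 down, and 118 changed at least 2-fold, 27 up and 91 down. At an unadjusted p under 0.05 there were 1774. The 2-fold counts again use fitted values. Examples are LOC344887, at chromosome 3, 185698542 to 185698601 (hg19), which was at least 4.85-fold lower (adjusted p = 0.000868, limma), and a transcript the array names lnc-BBC3-1, at chromosome 19, 47742558 to 47742617, at least 1.94-fold lower (adjusted p = 0.00125). These p-values belong to the fitted differences and not to the bounds. Both transcripts were at background on the SPARCL1 arrays, and they were chosen after their values were seen.

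Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 3756 changed genes and 384 at least 2-fold, and the highest of the others gave 0 and 0, so 1 split reached each count. The splits are too few for a share under 0.05.

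Metallothionein genes were higher in the SPARCL1 arrays. The tables argue against a slide difference as the whole cause, since the median of the metallothionein genes proper was 0.92 within slide 2, and against a gain of the chromosome 16 segment, since the 20 tested genes nearest the cluster (56624933 to 56718021), metallothionein pseudogenes left out, had a median log2 fold change of 0.0784. For a general response to zinc or another metal that acts through MTF1, a rise of SLC30A1 had been predicted. This was not met: its log2 fold change was -1.13. The test rests on 1 gene, which codes for a zinc exporter and itself changed, so it cannot decide about a response to zinc. Reading of the same transcript by several probes could not be told apart from separate rises: at most 26 of 60 bases matched between the MT1G probe and another risen one, but MT1F and MT1X shared 49, MT1F and MT1H 46, and MT1E and MT1B 49 (MT1B was chosen after its values were seen), and transcripts beyond the probes were not compared. A rise of several metallothionein genes tied to SPARCL1 overexpression may be a hypothesis, as may a difference between the cell populations that stable selection left, which the design does not separate from it.

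More of the genes changed at least 2-fold fell than rose. A lower signal on slide 1 is argued against by slide 2 alone, where 75.5% of such genes fell. Signal near the floor of detection stays open: among genes with a mean level over all 6 arrays above the median of the tested genes 27 of 54 such changes (50%) were falls, against 260 of 330 below it (Fisher's exact test, two-sided, p = 2.86e-05, over genes, which are not independent). Normexp, which damps dim signals by its offset, gave 57.6%, but among genes well above background on all 6 arrays 158 of 241 were falls (65.6%), under a filter partly decided by the change itself. That filter kept 158 of 287 falls and 83 of 97 rises. The lowest level called above background was lower on every vector array than on any SPARCL1 array, so the main filter let in dim genes more readily through the vector group. Scaling stays open: quantile normalization gave 68.8%, the percentile over detected probes 81.8% and array median scaling 61.8%, whose 95% Clopper-Pearson interval (56.8% to 66.6%) takes in the 60% set as the limit, and whether dim genes fell in the cells or in the measurement was not tested.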

How the results depend on the processing

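The fit within slide 2 and the percentile over detected probes were chosen after the data were seen. The signal over background set what could be tested: 44.8% of probes were above background on all 6 arrays. The 3756 changed genes became 1313 with no filter, 1698 with slide as a block and 1656 within slide 2, which rest on 1 SPARCL1 array, and 6400 unadjusted; the causes were not tested. With the replicate block there were 1586 changed genes and 362 at least 2-fold. Equal numbers did not deviate together (r across genes -0.0513, -0.101 and -0.0416). Deviations over 3 arrays per group, with slides mixed in the SPARCL1 group, cannot exclude a pairing of the samples. Leaving out 1 array gave 1844 to 3902 changed genes, 330 to 477 at least 2-fold and 7 to 8 lists. Both highest gene counts, 3902 and 477, came without SPARCL1 replicate 3, where slide and group coincide and the array of lowest weight is left out. The 384 genes at least 2-fold became 92 under normexp, whose offset shrinks folds of dim genes, and 244 with the filter on all 6 arrays, where fewer genes were tested. The 8 lists became 5 under quantile normalization, 5 in the authors' table, 0 with an estimated correlation and 25 with fry; the cause was not tested. Camera has no robust setting, so lists were not run there. The lists of cholesterol genes, metallothioneins, histones, mitochondrial transcripts and ATF4 genes passed in all 19 settings that keep the preset correlation, with adjusted p from 4.86e-12 to 7.83e-08, 3.54e-07 to 7.52e-05, 4.51e-08 to 0.000126, 0.000248 to 0.0156 and 0.00033 to 0.0222. NRF2 targets passed only with no filter (adjusted p = 0.0421) and Notch genes only with the mean over probes (0.045) among these 19. Ribosomal protein genes passed in 17, hypoxia genes in 14 and G1/S genes in 7, with reversal of the ribosomal median in the authors' table (-0.00433).

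H4C8 reversed with the mean over its probes (-0.204), since its probes differ in sign. With fry, which weighs genes otherwise than the median does, secreted WNT antagonists (median 0.242, adjusted p = 0.00105) and angiogenic factors (0.0122, adjusted p = 0.03) moved down. The SPARCL1 probe was at background on all 6 arrays, so its log2 differences are no folds and measure no change: 0.418 over all arrays, 0.0319 under normexp, 0.0742 under quantile normalization, 0.083 in the authors' table, 0.184 with slide as a block and within slide 2, and 0.333 to 0.535 leaving out 1 array. Of 1087 changed genes with several tested probes, 895 had the same sign in all and 60 had a probe of opposite sign at an unadjusted p under 0.05.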

Other observations

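The tests on the flanks of the pairs and on the run of chromosome 19 were chosen after the pairs and the run were seen. Of 23 p53 target genes 7 fell and 3 rose, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.209), with GDF15, a secreted stress cytokine gene, down with a log2 fold change of -1.33 and TP53INP1 with -1.06. Of 33 immediate-early genes, which respond within minutes to growth signals, 7 rose and 8 fell, also adjusted over the list alone (0.723). DUSP1, a phosphatase gene that limits MAP kinases, fell by 1.19 and KLF2 by 0.95, and DUSP2 by 2.32 with 2 of 3 SPARCL1 arrays above background. Of 21 YAP/TAZ target genes 3 rose and 4 fell, also adjusted over the list alone (0.998), with IGFBP3 down with -1.61, ANKRD1 with -1.07 and ARHGEF17 with -0.71, and WWC1 up by 0.66. Of 25 TGF-beta response genes 5 rose and 9 fell, also adjusted over the list alone (0.714), with PMEPA1 and BHLHE40 each up by 0.71 and ID3 down with -1.15 and ID1 with -0.69.

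Of 22 Notch pathway genes 1 rose and 5 fell, or 3 and 7 adjusted over the list alone (camera adjusted p = 0.452), with NOTCH3 down with -1.11 and its target HEYL with -0.62. Of 19 heat shock genes 1 rose and 4 fell, or 2 and 5 adjusted over the list alone (0.955), with HSPA1A down with -0.77. Of 22 unfolded protein response genes 1 rose and 1 fell, and 0 passed adjusted over the list alone (0.923). None of these lists passed with slide as a block or within slide 2.

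Genes changed at least 2-fold often lay next to each other. Among 16129 tested genes with a position, 25 neighbouring pairs both rose or both fell at least 2-fold, against a median of 6 and a highest count of 15 in 10000 shuffles (permutation p = 1e-04, the smallest they can give). The pairs include MMP1 with MMP3 and MMP3 with MMP13 on chromosome 11, IGFBP1 with IGFBP3 on chromosome 7, COL4A6 with COL4A5 on chromosome X and TNFSF9 with CD70 on chromosome 19. MMP13, IGFBP1, TNFSF9 and CD70 were chosen after their values were seen. Gained or lost segments that reach beyond the pairs are argued against as the general cause: the 20 tested genes nearest each pair had a median log2 fold change, taken in the direction of the pair, of 0.0251 over the 25 pairs (quartiles -0.03 and 0.11, highest 0.20). Shared control regions and segments no longer than a pair are possible explanations that were not tested. Some pairs belong to the same gene family, such as KRT81 with KRT86 and KCNJ18 with KCNJ12, named after their values were seen. Probes of such a pair may read the same transcript, which was tested only for metallothioneins. The shuffles do not keep such genes together, so their p-value does not address this.

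Over runs of 25 consecutive genes, the largest median was 0.54 in size, against 0.344 at the 95th percentile of the largest in 200 shuffles of the gene order, a limit that 105 of 15577 overlapping windows passed. Among the highest were windows of the histone genes on chromosome 6, a set fixed as a sign of RNA handling and scaling. These lay above 0 (largest median 0.52, from 26022181 to 26250588). Windows of zinc finger genes on chromosome 19 from 52448784 to 53666618 (-0.47) were also among the highest. The largest belonged to a run of 25 genes on chromosome 19, 36803485 to 38055552 (hg19), of which 20 carry zinc finger symbols; 15 fell, none rose, and the median was -0.54 (-0.56 within slide 2). A trend with signal level is argued against by genes matched in level to the 218 zinc finger genes of chromosome 19, whose median was 0.0031 against -0.32. A fall of all zinc finger genes alike is argued against as the whole cause by those on other chromosomes, with a median of -0.0705 over 279 genes. Of these 54 fell and 22 rose, against 1824 and 1920 over all genes. The genes were picked by symbol and not by type of zinc finger. A fall of a subfamily frequent on chromosome 19 therefore stays open. Loss of the segment stays open, since the 5 other genes of the run had a median of -0.54 but were part of the window picked for its size. Zinc finger genes elsewhere on chromosome 19 also lay low (median -0.29 over 198 genes, 73 down and 6 up), while 883 other genes of the chromosome had a median of 0.00, so a loss of this segment alone may not account for the pattern.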
